A study of Homo sapiens with 8 samples.

How the data were processed

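RNA sequencing libraries of 8 vehicle-labelled human Liver-Chips, 4 from day 3 and 4 from day 5, were analysed from 1 table of gene counts per library. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, total RNA was extracted with TRI Reagent and sequenced on an Illumina HiSeq instrument.

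The deposited values are whole-number counts of reads per gene, not normalised, made by the authors. Per the submitters' processing notes, Trimmomatic 0.36, STAR 2.5.2b, featureCounts and Subread 1.5.2 were used with the genome build GRCh38; the notes as used here give neither the role nor the order of each tool. The annotation release, whether counting used the strand, and how reads with several matches were treated are not given in the sources used here. Counts of genes that overlap on the other strand or have near-identical copies are therefore uncertain. Besides the genes whose overlap the results give, this holds for THY1 (10.7%), USP2 (17.5%), PER3 (10.7%), F11 (10.5%), CPT2 (11%), SPARC (7.9%), TPM4 (8.8%), TGFB1 (6.6%) and SLC51B (6.4%), by the share of their exonic bases that a gene on the other strand covers. OSGIN1 shares 13.9% with a gene on the same strand.

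The tables hold 57500 Ensembl gene identifiers, of which 56898 matched GENCODE release 29 and took their symbols, biotypes and GRCh38 coordinates from it (56410 also matched a separate table of gene names). GC content came from the transcripts of that release for 56845 genes. CPM values (counts scaled to a common library total) were computed here from the deposited counts with edgeR's TMM factors, which ranged from 0.902 to 1.03. Each value is the mean ± SD of 4 libraries. In total 518 genes (those on the Y chromosome, XIST and TSIX) were left out of the tests of genes and lists for privacy. They were kept in the library totals and library measures.

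Total counts ran from 37931813 to 56166886 per library. A floor of 3 counts corresponded to 0.0534 to 0.0791 CPM. Shares of single libraries carry exact Clopper-Pearson intervals at a level of 95%. Intervals and floors cover counting error only, since reads copied by PCR are not independent molecules. A chi-square comparison of the counts of all 12 within-day pairs of libraries, over genes with at least 20 counts in the pair, gave 7.53 to 286 per degree of freedom, so that no library was counted as a copy of another.

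Genes were filtered with filterByExpr, which left 17907, and tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, day as the only term) in R 4.3.3. P-values were adjusted by the Benjamini-Hochberg method and 0.05 was the threshold. Fold changes are day 5 over day 3. Lists of genes were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and adjusted over the 39 of 41 lists with at least 5 tested genes. The same test was run with the correlation estimated from the data, and the rotation test fry was run beside it. Scores are the mean over a list's genes of the deviation of log2 CPM from the 8-library mean. Library measures were compared by two-sided exact permutation tests over the 70 assignments of 4 against 4 libraries and adjusted over the 6 measures. Tables were handled with pandas 2.3.3 in Python 3.11.15 and plots drawn with matplotlib 3.10.9.

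The comparison, the tests, the lists, the rule for named genes and the alternatives were fixed before the data were examined, except where the text says otherwise. The rule named the 8 genes with the largest rise and the 8 with the largest fall among protein-coding genes past the threshold with a mean of at least 5 CPM and ranges of both days that did not overlap. It added the 2 genes of smallest p in each list with a call, and 14 genes in every case (among them ALB, CYP3A4, CYP1A2, CYP2E1, CYP7A1, HNF4A, PECAM1, STAB2, CD163, COL1A1, ACTA2, KRT19 and MKI67). HLA, immunoglobulin and T cell receptor genes and a fixed set of genes often deleted in people were not named. CYP2A6, of which deleted alleles are also known, was not in that set. The 41 lists held 894 entries, of which 888 matched a gene in the tables and 6 did not, for 839 different genes. They covered liver functions (secreted plasma proteins, acute phase proteins, complement and coagulation, cytochrome P450, phase II conjugation, transporters, bile acids, amino acids, glucose, lipids, transcription factors, receptor targets), stress and signalling programmes, and markers of the cell types in the chip, of blood cells and of RNA without poly(A) tails.

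Alternatives were RLE, upper quartile and library-total scaling, no filter on low counts or a filter of 1 CPM in 4 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, a GC correction (lowess offsets with a span of 0.3), both together, removal of mitochondrially encoded genes, each library left out in turn, glmTreat against a fold of 1.5 and a threshold of 0.01. Leaving out day 3 replicates 1 and 2 together was added after seeing the data. Counts of list genes past the threshold with 1 library left out are given only where they moved by more than 1.5 times. Smaller moves of these counts are not printed, so a library that is not mentioned may still change a count.

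The tests were tried on simulated counts with the means and library sizes of these samples, with 17681 genes tested. In them 200 single genes were changed, 50 at each fold. The genes of the cell cycle and ribosomal protein lists were changed as well, and calls of these count in the totals of calls below. Counts were drawn with edgeR's own dispersion estimates, which may favour edgeR in the comparison of tools. For day 5 against day 3, edgeR recovered 34% of genes changed 1.5-fold, 72% at 2-fold, 84% at 3-fold and 88% at 4-fold, with 8 false calls among 180. DESeq2 recovered 52%, 74%, 90% and 86% at these folds with 51 false calls among 255, limma-voom made 8 among 176, and edgeR with the replicate block 12 among 155. Camera found both changed lists and none of 37 unchanged ones, and fry found both and 1 of 37. The simulated genes were drawn independently of each other, whereas the correlation estimated from the real data was 0.70 for the ribosomal list. The simulation therefore does not show how often lists of correlated genes are called falsely.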

Results

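RNA was sequenced from human Liver-Chips, microfluidic culture devices in which primary human hepatocytes line an upper channel. Liver sinusoidal endothelial cells, Kupffer cells (the resident macrophages of the liver) and stellate cells (its matrix-producing pericytes) line the lower channel, so that 4 cell types were present. The series held 8 libraries from vehicle-labelled chips, 4 labelled day 3 and 4 labelled day 5. The labels give the source as hepatocytes; which channel the RNA came from, and what the vehicle was, are not given in the sources used here. Total counts were 37931813, 43915702, 48283494 and 56166886 for day 3 replicates 1 to 4, and 41511235, 43265019, 53530319 and 54966173 for day 5 replicates 1 to 4. At these depths a count of 3 corresponded to 0.0534 to 0.0791 CPM (the count of a gene per the library total, scaled to a common total). Nothing in the labels says whether the chips came from separate donors or culture runs, so p-values measure only the spread between these samples, which may be technical.

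Over all libraries ALB, HP, MT-CO1, C3 and FN1 had the highest mean counts. The 10 most abundant genes of each library took 12.5% ± 1.59 and 11.6% ± 0.263 of its counts on day 3 and day 5 (mean ± SD, n = 4 each; two-sided exact permutation p = 0.400). Albumin alone took 3.44% ± 0.409 and 2.79% ± 0.137 (exact permutation p = 0.0571, adjusted p = 0.343). Mitochondrially encoded genes took 5.22% ± 1.11 and 6.04% ± 0.177 (exact permutation p = 0.343), with lower shares in day 3 replicates 1 and 2 (3.87% and 4.76%) than in day 3 replicates 3 and 4 (both 6.12%). The exact 95% Clopper-Pearson intervals of the lower shares, 3.86 to 3.88% and 4.756 to 4.769%, cover counting error only. Protein-coding genes took 98.6% ± 0.101 and 98.7% ± 0.0439 (exact permutation p = 0.114). Genes at 1 CPM or more numbered 13901 ± 205 and 13947 ± 44.4 (exact permutation p = 0.80). Total counts did not differ past the test either (exact permutation p = 0.743). With 4 against 4 libraries the smallest p of this test is 0.0286, and the adjusted p of the 6 measures ran from 0.343 to 0.80.

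In a principal component analysis of log2 CPM, the first component (34.1% of the variance) set day 3 replicate 1 (-60.3) and day 3 replicate 2 (-27.6) apart from the other 6 libraries, which lay between 7.004 and 21.3. The second component (26.5%) held the 4 day 5 libraries between 11.5 and 25.1 and day 3 replicates 2 to 4 between -36.8 and -22.1. Day 3 replicate 1, at 17.6, lay among the day 5 libraries on that component. Correlations of log2 CPM across genes, which are not independent replicates, ran from 0.974 to 0.993 between day 3 libraries and from 0.99 to 0.994 between day 5 libraries.

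**Figure D1:**
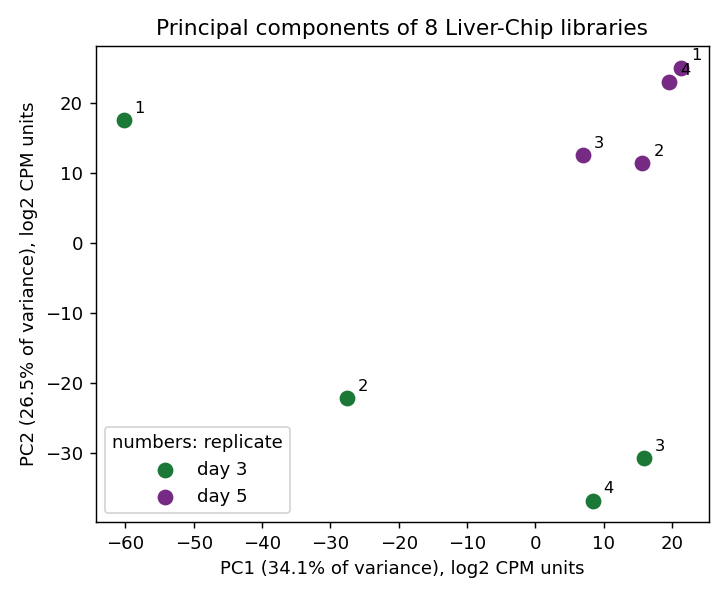
Each point is 1 of 8 libraries, placed by its scores on the first principal component (x axis, 34.1% of the variance) and the second (y axis, 26.5%) of log2 CPM, with green for day 3, purple for day 5 and the replicate number beside it. Day 3 replicates 1 and 2 sit at -60.3 and -27.6 on the first component, and the other 6 libraries between 7.004 and 21.3.

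The comparison the design implies asks how gene expression in vehicle-labelled chips differed between day 3 and day 5. On day 5, 16 of 30 genes for extracellular matrix and 11 of 22 stellate markers were higher, among them COL1A2 (111 ± 21.3 and 349 ± 119.6 CPM on day 3 and day 5), SPARC (87.8 ± 6.94 and 230.2 ± 57.8 CPM) and LOX (6.79 ± 0.714 and 23.3 ± 9.69 CPM; all mean ± SD, n = 4 each). The chemokine gene CXCL8 was 4.07-fold higher (25.3 ± 8.19 and 103 ± 15.3 CPM). Of 20 genes for drug-metabolising cytochrome P450 enzymes, 9 were lower, CYP2B6 by 3.46-fold (678 ± 146 and 196 ± 23.7 CPM) and CYP2A6 by 1.88-fold (1596 ± 134 and 848 ± 57.7 CPM). Of 25 cholesterol synthesis genes 7 were lower, TM7SF2 by 1.801-fold, and of 27 fatty acid oxidation genes 8, ACSL1 by 1.69-fold. None of these lists passed camera with an estimated correlation. For each gene named here the 4 day 5 libraries lay wholly above or wholly below the 4 day 3 libraries. The naming rule required this of LOX, CXCL8 and CYP2B6, and the others were named for the smallest p in their lists. The separation is therefore no separate support.

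Of 17907 genes tested, 938 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of these, 519 were higher and 419 lower on day 5, and 826 were protein coding. At a fold of 2 or more, 196 were higher and 63 lower. The ranges of both days did not overlap for 2887 genes, 16.1% of those tested, against the 2.86% that chance gives on average. Genes vary together between libraries, so a single arbitrary division may lie far from this average. Its spread over divisions was not computed. Scaling by library totals alone called 561 genes higher and 227 lower, a higher share of 71.2% against 55.3%. A test against a minimum fold of 1.5 called 2 genes, CYP2B6 and the cyclin D2 gene CCND2, the latter chosen after its values were seen. The number of calls depended on single libraries: it was 2041 without day 3 replicate 1, 407 without day 3 replicate 4, and 177, 437, 488 and 106 without day 5 replicates 1 to 4. In these 8 fits 936 of the 938 genes kept their direction, the other 2 were not tested in every fit, and 100 were called in all 8. Without day 3 replicates 1 and 2, an alternative chosen after seeing the data, 2589 genes were higher and 2430 lower, with 920 of the 938 among them. Of 75 genes chosen by a rule fixed before the data were examined, 57 passed, 24 of them in all 8 fits.

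Matrix and stellate cell genes were higher together on day 5. Of 30 tested genes for extracellular matrix and its turnover, 16 rose and 14 did not pass (21 rose when adjusted over the list alone), with a median log2 fold change of 0.80. The list passed (camera adjusted p = 2.0e-12; adjusted p = 0.139 with an estimated correlation). Of 22 stellate cell and myofibroblast markers, 11 rose and 11 did not pass (16 rose when adjusted over the list alone), with a median of 1.28 (camera adjusted p = 7.2e-11; adjusted p = 0.139 with an estimated correlation). COL1A1, COL1A2, COL3A1, SPARC and TIMP1 stand in both lists. COL1A2 (ENSG00000164692), a chain of type I collagen on chromosome 7, 94394561 to 94431232 (GRCh38), rose 3.15-fold (log2 1.66, SE 0.23, adjusted p = 0.0092). SPARC (ENSG00000113140), a collagen-binding matrix protein on chromosome 5, 151661096 to 151687165, rose 2.62-fold (log2 1.39, SE 0.16, adjusted p = 0.0073). LOX (ENSG00000113083), which encodes the enzyme that cross-links collagen and lies on chromosome 5, 122063195 to 122078285, rose 3.43-fold (log2 1.78, SE 0.25, adjusted p = 0.0092). COL1A1 rose 3.12-fold (274 ± 64.6 and 856 ± 281 CPM, adjusted p = 0.011; 0.052 without day 5 replicate 4). POSTN, the matricellular protein periostin, rose by log2 1.88 (adjusted p = 0.032; 0.068 to 0.105 without day 3 replicates 2 and 4 and day 5 replicates 1, 3 and 4 in turn), and THY1, a fibroblast surface protein, by 1.77 (adjusted p = 0.016; 0.058 to 0.069 without day 5 replicates 1 and 4 in turn). ACTA2, which encodes smooth muscle actin and shares 12.8% of its exonic bases with FAS on the other strand, gave 24.9 ± 5.53 and 44.6 ± 16.6 CPM and did not pass (adjusted p = 0.11). The matrix count was 8 without day 3 replicate 4 or day 5 replicate 1 and 4 without day 5 replicate 4. The stellate count was 6 without day 5 replicate 1 and 3 without day 5 replicate 4.

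Targets of TGF-beta and YAP signalling and cytoskeletal genes were also higher. Of 20 TGF-beta and YAP targets, 8 rose and 12 did not pass (12 rose when adjusted over the list alone), with a median log2 of 0.56 (camera adjusted p = 2.0e-08; adjusted p = 0.139 with an estimated correlation). TAGLN of this list was also counted among the stellate genes. CCN1, a secreted matricellular protein, gave 75.7 ± 13.9 and 153 ± 14.7 CPM (log2 1.01, adjusted p = 0.0086), and TGFB1, which encodes the ligand itself, 12.9 ± 1.37 and 20.4 ± 1.55 CPM (log2 0.67, adjusted p = 0.0093). Of 27 genes of the actin cytoskeleton and hepatocyte keratins, 11 rose and 16 did not pass (14 rose when adjusted over the list alone), with a median of 0.26 (camera adjusted p = 8.9e-09; adjusted p = 0.139 with an estimated correlation). TPM4, a tropomyosin, rose by log2 0.73 (adjusted p = 0.0073). TUBB6, a tubulin that shares 20.3% of its exonic bases with AFG3L2 on the other strand, rose by 0.65 (adjusted p = 0.0092). VIM, which encodes the intermediate filament protein vimentin and overlaps VIM-AS1 over 12.4% of its exonic bases, rose 2.01-fold (adjusted p = 0.012; 0.057 without day 5 replicate 4). It was the 1 gene past the test among 19 biliary and dedifferentiation markers (1 when adjusted over the list alone), whose median was 0.17 (camera adjusted p = 0.0092, 0.067 without day 5 replicate 4; adjusted p = 0.254 with an estimated correlation). The biliary markers KRT19 (30.5 ± 9.94 and 31.7 ± 10.9 CPM, adjusted p = 0.937) and EPCAM (11.7 ± 3.17 and 17.8 ± 1.13 CPM, adjusted p = 0.076; 0.026 without day 3 replicate 3) did not pass. The TGF-beta and YAP count was 4 without day 5 replicate 1 and 3 without day 5 replicate 4. The cytoskeletal count was 6 without day 3 replicate 4 or day 5 replicates 2 or 3, 5 without day 5 replicate 1 and 3 without day 5 replicate 4. The biliary count was 2 without day 3 replicates 2, 3 or 4 and 0 without day 5 replicate 4.

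Immediate early genes, which respond within minutes to growth and stress signals, were higher as a list (17 tested, median log2 0.40, camera adjusted p = 6.0e-04; adjusted p = 0.1397 with an estimated correlation). EGR1, FOS and FOSL1 rose and 14 did not pass (7 rose and 1 fell when adjusted over the list alone). EGR1 (ENSG00000120738; chromosome 5, 138465490 to 138469315), a zinc finger transcription factor, gave 41.1 ± 7.54 and 111 ± 10.9 CPM (log2 1.43, SE 0.13, adjusted p = 0.0038). FOS gave 4.97 ± 1.26 and 12.2 ± 2.27 CPM (log2 1.303, adjusted p = 0.012), and FOSL1, chosen after its values were seen, rose by log2 0.73 (adjusted p = 0.028, and up to 0.105 with 1 library left out, under 0.05 in 3 of 8 fits). Of 22 inflammatory cytokines and NF-kB targets, the chemokines CXCL8, CCL2 and CXCL1 rose, LCN2 fell and 18 did not pass (6 rose and 1 fell when adjusted over the list alone). The median of this list was 0.24 (camera adjusted p = 0.0063, 0.113 without day 3 replicate 3; adjusted p = 0.517 with an estimated correlation). CXCL8 (ENSG00000169429; chromosome 4, 73740506 to 73743716), a neutrophil attractant, rose by log2 2.03 (SE 0.21, adjusted p = 0.0057), and CCL2, a monocyte attractant, by 1.399 (adjusted p = 0.012; 0.057 without day 5 replicate 4). CXCL1 rose by 1.397 (adjusted p = 0.026, under 0.05 in 3 of 8 fits) and LCN2, which encodes a secreted siderophore-binding protein, fell by 1.48 on the log2 scale (adjusted p = 0.015, under 0.05 in 7 of 8 fits); both were chosen after their values were seen. Day 3 replicate 1 had an inflammatory score, a mean deviation of log2 CPM from the 8-library mean, of 0.34, against -0.58 to -0.14 in the other day 3 libraries. The immediate early count was 7 without day 3 replicate 1. Immediate early genes that fell numbered 1 without day 3 replicate 3. The inflammatory count was 7 without day 3 replicate 1, 5 without day 5 replicate 3 and 1 without day 5 replicate 4. Inflammatory genes that fell numbered 0 without day 5 replicate 4.

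Cell cycle and ribosomal protein genes were higher as lists with few single calls. Of 35 cell cycle genes, UBE2C, CDC20 and TPX2, all of mitosis, rose and 32 did not pass (12 rose when adjusted over the list alone), with a median log2 of 0.64 (camera adjusted p = 1.0e-07; adjusted p = 0.262 with an estimated correlation). UBE2C (0.415 ± 0.133 and 1.204 ± 0.402 CPM, adjusted p = 0.034; 0.062 to 0.118 without day 3 replicates 2 and 4 and day 5 replicates 1, 2 and 4 in turn) and CDC20 (1.15 ± 0.335 and 2.86 ± 0.981 CPM, adjusted p = 0.0404; 0.051 to 0.132 without day 3 replicates 2, 3 and 4 and day 5 replicates 1, 2 and 4 in turn) lay at low levels. TPX2, chosen after its values were seen, rose by 1.02 (adjusted p = 0.045, and up to 0.145 with 1 library left out, under 0.05 in 2 of 8 fits), and MKI67, the proliferation marker, gave 3.001 ± 0.947 and 6.01 ± 2.05 CPM (adjusted p = 0.082). Of 37 ribosomal protein genes, 5 rose and 32 did not pass, while 29 rose when adjusted over the list alone, and all 37 fold changes were above 0. Their median was 0.19 (camera adjusted p = 3.5e-13; adjusted p = 0.2597 with an estimated correlation). RPS3 rose by 0.35 (adjusted p = 0.014; 0.064 to 0.069 without day 5 replicates 1 and 4 in turn) and RPSA by 0.33 (adjusted p = 0.0196; 0.057 to 0.087 without day 3 replicate 4 and day 5 replicates 1, 2 and 4 in turn). RPS18 (0.33; adjusted p = 0.026, under 0.05 in 2 of 8 fits), RPL23 (0.27; adjusted p = 0.025, under 0.05 in 3 of 8 fits) and RPS4X (0.26; adjusted p = 0.037, under 0.05 in 2 of 8 fits) were chosen after their values were seen. Ribosomal protein genes have many processed pseudogenes, and how reads with several matches were counted is not given in the sources used here, so single members are uncertain. The cell cycle scores of day 5 replicates 1 to 4 were 0.49, 0.12, -0.03 and 0.51, beside stellate scores of 0.96, 0.37, 0.11 and 0.70. The cell cycle count was 6 without day 5 replicate 3 and 0 without day 3 replicates 2 or 4 or day 5 replicates 1, 2 or 4. The ribosomal count was 9 without day 3 replicate 2, 3 without day 3 replicate 3, 2 without day 5 replicate 3, 1 without day 3 replicate 4 or day 5 replicate 2 and 0 without day 5 replicates 1 or 4. With all libraries, 20 cell cycle and 30 ribosomal genes had an unadjusted p under 0.05, DESeq2 called 11 and 21, and limma-voom 1 and 5.

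Drug-metabolising cytochrome P450 genes were lower on day 5. Of 20 tested, 9 fell and 11 did not pass (10 fell when adjusted over the list alone), with a median log2 fold change of -0.55 (camera adjusted p = 5.5e-08; adjusted p = 0.139 with an estimated correlation). CYP2B6 (ENSG00000197408; chromosome 19, 40991299 to 41018398), whose enzyme metabolises bupropion and efavirenz, fell by 1.79 on the log2 scale (SE 0.15, adjusted p = 0.0033). CYP2A6 (ENSG00000255974; chromosome 19, 40843538 to 40850447), whose enzyme is the main nicotine oxidase, fell by 0.91 (SE 0.09, adjusted p = 0.0038). CYP2C8 (371 ± 108 and 157 ± 15.3 CPM, adjusted p = 0.013; 0.053 to 0.062 without day 5 replicates 1 and 4 in turn) also fell. P450 genes have close paralogs and pseudogenes, so that single members, CYP2A6 and CYP2B6 among them, are uncertain where reads matched several genes. The day 3 libraries were not alike in this group. CYP3A4, whose enzyme metabolises the widest range of drugs in the liver, gave 1254 and 1263 CPM in day 3 replicates 1 and 2 and 4648 and 4033 in day 3 replicates 3 and 4. On day 5 it gave 2243 ± 90.3 CPM, and the difference did not pass (adjusted p = 0.704). CYP1A2 was at 115 CPM in day 3 replicate 1 and between 759 and 887 in the other day 3 libraries, against 532 ± 28.8 on day 5 (adjusted p = 0.759; 0.0022 without day 3 replicate 1). CYP2E1, which shares 23% of its exonic bases with SYCE1 on the other strand, was at 550.4 CPM in day 3 replicate 1 and at 47.7, 29.3 and 45.8 CPM in day 3 replicates 2 to 4, against 38.5 ± 12.4 on day 5 (log2 -2.13, adjusted p = 0.204; log2 -0.0962 without day 3 replicate 1). The P450 count was 4 without day 5 replicate 4. Without day 3 replicates 1 and 2, 16 P450 genes fell, CYP3A4 among them (log2 -0.95, adjusted p = 3.5e-05). These libraries had the lowest CYP3A4 values and P450 scores of day 3, so that leaving them out, chosen after seeing the data, favours a fall.

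NR1I3 (ENSG00000143257; chromosome 1, 161229666 to 161238302), the constitutive androstane receptor CAR that drives CYP2B6 transcription, fell 2.11-fold (46.6 ± 8.55 and 22.04 ± 1.68 CPM, log2 -1.08, SE 0.12, adjusted p = 0.0073). It shares 20% of its exonic bases with TOMM40L on the other strand, which gave 40.4 and 40.02 CPM. Of 22 hepatocyte transcription factors and nuclear receptors, NR1I3, FOXA2 and ONECUT1 fell and 19 did not pass (4 fell when adjusted over the list alone), with a median of -0.15 (camera adjusted p = 0.0081; adjusted p = 0.139 with an estimated correlation). FOXA2 fell by 0.40 on the log2 scale (adjusted p = 0.014; 0.052 to 0.069 without day 5 replicates 1 and 4 in turn) and ONECUT1, chosen after its values were seen, fell by 0.38 (adjusted p = 0.037, under 0.05 in 2 of 8 fits), while HNF4A gave 415 ± 66.5 and 374 ± 11.2 CPM (adjusted p = 0.464; 0.025 without day 3 replicate 1). Of 17 targets of the xenobiotic receptors PXR, CAR and AhR, 7 fell and 10 did not pass (8 fell when adjusted over the list alone; median -0.31, camera adjusted p = 0.0017; adjusted p = 0.139 with an estimated correlation). Those that fell were P450 genes also counted above, apart from ALAS1, the rate-limiting enzyme of heme synthesis, which fell by 0.72 (adjusted p = 0.016, under 0.05 in 5 of 8 fits) and was chosen after its values were seen. Of 26 genes of phase II conjugation, EPHX1 and GSTA1 fell and 24 did not pass (6 fell and 1 rose when adjusted over the list alone). The median of this list was -0.24 (camera adjusted p = 0.014, 0.084 without day 3 replicate 3, 0.062 without day 3 replicate 4; adjusted p = 0.4496 with an estimated correlation). EPHX1, microsomal epoxide hydrolase, gave 1169 ± 100.1 and 716 ± 39.8 CPM (adjusted p = 0.00801), and GSTA1, which has close paralogs, 220.4 ± 41.05 and 142 ± 11.8 CPM (adjusted p = 0.027; 0.054 to 0.104 without day 3 replicates 3 and 4 and day 5 replicates 1, 2, 3 and 4 in turn). The transcription factor count was 6 without day 3 replicate 1 and 1 without day 5 replicates 1 or 4. The receptor target count was 3 without day 5 replicate 1 and 2 without day 5 replicate 4. Receptor target genes that rose numbered 1 without day 3 replicate 1. The conjugation count was 9 without day 3 replicate 1 and 1 without day 3 replicates 3 or 4 or day 5 replicates 1, 2, 3 or 4. Conjugation genes that rose numbered 1 without day 3 replicates 1, 2 or 3.

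Of 24 hepatic transporters, 7 fell and 17 did not pass (10 fell when adjusted over the list alone), with a median of -0.24 (camera adjusted p = 0.00101; adjusted p = 0.254 with an estimated correlation). ABCG8, a subunit of a sterol exporter, fell by 0.58 on the log2 scale (adjusted p = 0.00801), and SLC51B, a subunit of a bile acid exporter, by 1.01 (4.46 ± 0.358 and 2.21 ± 0.292 CPM, adjusted p = 0.0086). SLC51B, ABCB11, SCP2 and CYP8B1 fell among 18 genes of bile acid synthesis and FXR targets, and 14 did not pass (4 fell when adjusted over the list alone). The median of this list was -0.27 (camera adjusted p = 0.0063; adjusted p = 0.254 with an estimated correlation). ABCB11, the bile salt export pump, fell by 0.56 (adjusted p = 0.022; 0.057 to 0.091 without day 3 replicate 4 and day 5 replicates 1, 3 and 4 in turn), while SCP2 (log2 -0.54, adjusted p = 0.040, under 0.05 in 2 of 8 fits) and CYP8B1 (-0.41, adjusted p = 0.041, under 0.05 in 3 of 8 fits) were chosen after their values were seen. CYP7A1, the rate-limiting enzyme of bile acid synthesis, ranged from 2.66 to 55.3 CPM on day 3 and gave 17.2 ± 2.44 on day 5 (adjusted p = 0.601). The transporter count was 4 without day 3 replicate 4 and 3 without day 5 replicates 1, 3 or 4. Transporter genes that rose numbered 1 without day 3 replicate 1. The bile acid count was 7 without day 3 replicate 1, 2 without day 3 replicate 3 or day 5 replicates 2 or 3 and 1 without day 3 replicate 4 or day 5 replicates 1 or 4. Bile acid genes that rose numbered 1 without day 3 replicate 1.

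Genes of lipid metabolism were lower on day 5. Of 25 cholesterol synthesis genes, 7 fell and 18 did not pass, and 20 fell when adjusted over the list alone (median log2 -0.33, camera adjusted p = 7.2e-11; adjusted p = 0.139 with an estimated correlation). TM7SF2 (ENSG00000149809; chromosome 11, 65111845 to 65116384), a sterol reductase, gave 88.1 ± 7.55 and 48.9 ± 2.05 CPM (log2 -0.85, SE 0.07, adjusted p = 0.0033), and MVD, mevalonate diphosphate decarboxylase, 285 ± 27.8 and 181 ± 11.7 CPM (adjusted p = 0.0086). Of 27 genes of fatty acid oxidation and ketogenesis, 8 fell and 19 did not pass (10 fell when adjusted over the list alone; median -0.28, camera adjusted p = 1.8e-07; adjusted p = 0.052 with an estimated correlation). ACSL1, which activates long-chain fatty acids, gave 1875 ± 245 and 1111 ± 41.3 CPM (log2 -0.76, adjusted p = 0.0092), and CPT2, of the mitochondrial carnitine shuttle, 57 ± 2.17 and 41.8 ± 1.43 CPM (log2 -0.45, adjusted p = 0.0082). Of 23 genes of fatty acid and triglyceride synthesis, 6 fell and 17 did not pass (8 fell when adjusted over the list alone; median -0.27, camera adjusted p = 1.7e-05; adjusted p = 0.165 with an estimated correlation). MLXIPL, the carbohydrate-responsive transcription factor ChREBP, gave 755 ± 38 and 518 ± 18.4 CPM (log2 -0.54, adjusted p = 0.0081), and ELOVL5, a fatty acid elongase, fell by 0.44 (adjusted p = 0.011; 0.0504 to 0.0602 without day 5 replicates 1 and 4 in turn). The cholesterol count was 14 without day 3 replicate 1, 11 without day 3 replicate 3, 4 without day 5 replicate 2, 3 without day 3 replicate 4 or day 5 replicate 3 and 2 without day 5 replicates 1 or 4. The fatty acid oxidation count was 5 without day 3 replicate 3 or day 5 replicate 2, 4 without day 3 replicate 4 or day 5 replicate 3, 3 without day 5 replicate 1 and 2 without day 5 replicate 4. The fatty acid synthesis count was 1 without day 5 replicates 1 or 4.

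Amino acid, glucose, clock and NRF2 genes were lower as lists with fewer calls. Of 27 genes of the urea cycle and amino acid catabolism, GNMT, GLS2, CBS and MAT1A fell and 23 did not pass (10 fell when adjusted over the list alone), with a median log2 of -0.38 (camera adjusted p = 8.5e-05; adjusted p = 0.254 with an estimated correlation). GNMT (ENSG00000124713; chromosome 6, 42960758 to 42963880), glycine N-methyltransferase, fell 3.96-fold (45.1 ± 16.2 and 11.4 ± 1.42 CPM, log2 -1.99, SE 0.27, adjusted p = 0.0092). GLS2 (8.23 ± 2.63 and 2.55 ± 0.216 CPM, adjusted p = 0.0103; 0.053 without day 5 replicate 4) is uncertain, since 77.1% of its exonic bases overlap SPRYD4 on the other strand. Whether counting used the strand is not given in the sources used here. CBS (log2 -0.59, adjusted p = 0.012, under 0.05 in 7 of 8 fits) and MAT1A (-0.33, adjusted p = 0.0403, under 0.05 in 1 of 8 fits) were chosen after their values were seen. Of 17 genes of gluconeogenesis and glycogen, PCK2 fell (log2 -0.60, adjusted p = 0.028; 0.051 to 0.109 without day 3 replicates 3 and 4 and day 5 replicates 1, 2, 3 and 4 in turn) and 16 did not pass (3 fell when adjusted over the list alone). The median of this list was -0.29 (camera adjusted p = 0.029, 0.074 without day 3 replicate 4, 0.052 without day 5 replicate 3; adjusted p = 0.254 with an estimated correlation). PPP1R3C, a glycogen-targeting phosphatase subunit (adjusted p = 0.0603; 0.018 without day 3 replicate 1 and 0.039 without day 3 replicate 2), and PCK1, the cytosolic enzyme (12.9 ± 3.21 and 6.47 ± 2.36 CPM, adjusted p = 0.067; 0.033 without day 3 replicate 1 and 0.047 without day 5 replicate 3), did not pass. Of 19 circadian clock genes, PER3, TEF and NPAS2 fell and 16 did not pass (8 fell when adjusted over the list alone; median -0.37, camera adjusted p = 8.5e-05; adjusted p = 0.139 with an estimated correlation). TEF, a clock-output transcription factor, gave 17.2 ± 3.08 and 8.98 ± 0.378 CPM (adjusted p = 0.0092), PER3 fell by 1.05 (adjusted p = 0.014; 0.0596 to 0.069 without day 5 replicates 1 and 4 in turn) and NPAS2, chosen after its values were seen, fell by 0.26 (adjusted p = 0.037, under 0.05 in 2 of 8 fits). The time of day of sampling is not given in the sources used here. Of 21 genes of NRF2 and oxidative stress, OSGIN1, ABCC2 and SRXN1 fell and 18 did not pass (4 fell and 1 rose when adjusted over the list alone). The median was -0.13 (camera adjusted p = 0.019, 0.057 without day 3 replicate 2, 0.052 without day 5 replicate 3; adjusted p = 0.254 with an estimated correlation). OSGIN1 fell by 0.74 (adjusted p = 0.015; 0.055 to 0.069 without day 5 replicates 1 and 4 in turn), ABCC2 fell by 0.46 (adjusted p = 0.016; 0.052 to 0.076 without day 5 replicates 1, 3 and 4 in turn), and SRXN1, chosen after its values were seen, fell by 0.40 (adjusted p = 0.026, under 0.05 in 3 of 8 fits). The amino acid count was 15 without day 3 replicate 1 and 1 without day 5 replicate 4. The gluconeogenesis count was 5 without day 3 replicate 1, 2 without day 3 replicate 2 and 0 without day 3 replicates 3 or 4 or day 5 replicates 1, 2 or 4. The clock count was 7 without day 3 replicate 1 and 1 without day 5 replicates 1 or 4. The NRF2 count was 5 without day 3 replicate 1 and 0 without day 5 replicates 1 or 4. NRF2 genes that rose numbered 1 without day 3 replicate 1 or day 5 replicate 3.

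**Figure D2:**
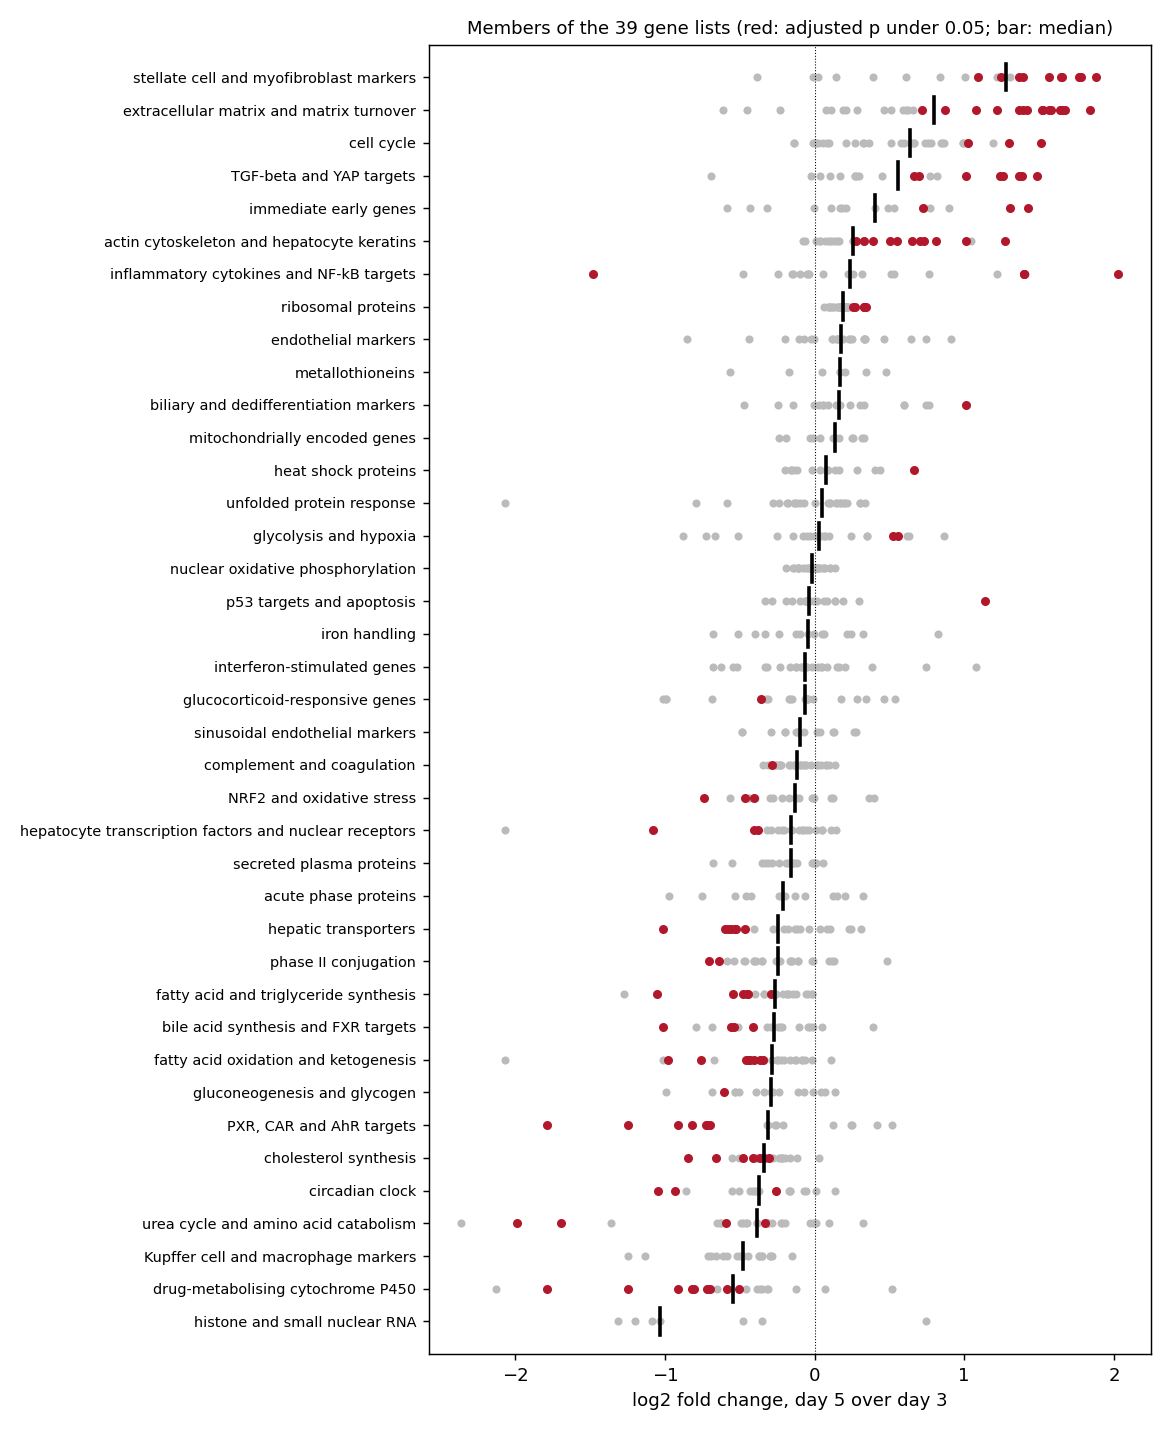
Each point is a tested gene of 1 of 39 lists fixed before the data were examined (y axis), placed by its log2 fold change of day 5 over day 3 (x axis). Red points passed an adjusted p of 0.05 over all genes, grey points did not, and black bars mark medians, which lie at 1.28 for the stellate list, 0.80 for the matrix list and -0.55 for the P450 list.

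Markers of the other cell types in the chip did not pass gene by gene. None of 24 endothelial markers passed in edgeR, with all genes or adjusted over the list alone (5 at an unadjusted p under 0.05, 1 in DESeq2 and 0 in limma-voom). Their median was 0.17 (camera adjusted p = 0.017, 0.123 without day 3 replicate 1, 0.1304 without day 5 replicate 2; adjusted p = 0.595 with an estimated correlation), and PECAM1, an endothelial adhesion molecule, gave 13.9 ± 0.979 and 16.5 ± 2.98 CPM. None of 14 sinusoidal endothelial markers passed in edgeR (0 at an unadjusted p under 0.05, 0 in DESeq2 and 0 in limma-voom; median -0.09, list adjusted p = 0.873), and STAB2, a sinusoidal scavenger receptor, lay at 0.405 ± 0.086 and 0.329 ± 0.063 CPM. None of 21 Kupffer cell and macrophage markers passed in edgeR (1 at an unadjusted p under 0.05, 0 in DESeq2 and 0 in limma-voom), while all 21 fold changes were below 0, with a median of -0.48. The Kupffer list did not pass with all libraries (camera adjusted p = 0.089; 0.039 without day 3 replicate 1, 0.0038 without day 3 replicate 3, 1.5e-04 without day 5 replicate 3). The Kupffer score was 1.15, 1.34 and 1.32 in day 3 replicates 2 and 4 and day 5 replicate 3, and between -0.93 and -0.58 in the other 5 libraries. CD163, a Kupffer cell receptor, gave 20.6 ± 11.7 and 16.2 ± 10.5 CPM. Sinusoidal genes that fell numbered 1 without day 3 replicate 3. Kupffer genes that rose numbered 1 without day 3 replicate 1. Of lymphocyte and erythrocyte markers, 2 and 0 genes were abundant enough to test, and neither of the former passed.

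Plasma protein genes were lower by a small median and passed as a list only in camera with the preset correlation. The list score differed by -0.104 between days (exact permutation p = 0.514, a test not fixed beforehand), and fry did not call the list (adjusted p = 0.1468). None of 18 secreted plasma protein genes passed in edgeR (5 at an unadjusted p under 0.05, 4 in DESeq2 and 0 in limma-voom), with a median log2 of -0.16 (camera adjusted p = 0.024, 0.284 without day 3 replicate 1, 0.063 without day 3 replicate 4, 0.051 without day 5 replicate 4; adjusted p = 0.485 with an estimated correlation). ALB, which encodes albumin, gave 35006 ± 3145 and 27386 ± 1320.2 CPM (adjusted p = 0.103; 0.035 without day 3 replicate 1). F11, coagulation factor XI, fell by 0.29 on the log2 scale (adjusted p = 0.032; 0.069 to 0.126 without day 3 replicates 3 and 4 and day 5 replicates 1, 3 and 4 in turn) among 26 complement and coagulation genes (list adjusted p = 0.119; 6.1e-04 without day 3 replicate 2), and PLG, plasminogen, did not pass (adjusted p = 0.068; 0.017 without day 3 replicate 2). KLF9 fell by 0.36 (adjusted p = 0.016; 0.054 to 0.082 without day 3 replicate 4 and day 5 replicates 1, 3 and 4 in turn) among 21 glucocorticoid-responsive genes (list adjusted p = 0.932; 2 fell and 1 rose when adjusted over the list alone). The upper medium held dexamethasone, a glucocorticoid, at 100 nM. PFKP, a phosphofructokinase (log2 0.56, adjusted p = 0.011; 0.055 without day 5 replicate 4), and PKM, pyruvate kinase (log2 0.52, adjusted p = 0.043; 0.074 to 0.142 without day 3 replicate 4 and day 5 replicates 1, 2, 3 and 4 in turn), rose among 25 genes of glycolysis and hypoxia (list adjusted p = 0.117; 0.029 without day 3 replicate 1; 4 rose and 1 fell when adjusted over the list alone). HSPA1B, whose paralog HSPA1A is nearly identical, rose by 0.67 (adjusted p = 0.035; 0.078 to 0.091 without day 3 replicate 4 and day 5 replicates 1, 2, 3 and 4 in turn) among 16 heat shock genes (list adjusted p = 0.116; 0.021 without day 3 replicate 1, 0.0022 without day 3 replicate 2). HSPB8, a small heat shock protein, did not pass (adjusted p = 0.135; 0.0051 without day 3 replicate 1). PMAIP1, which encodes the apoptosis factor NOXA, rose by 1.14 (adjusted p = 0.018; 0.072 without day 5 replicate 4) among 20 p53 targets (list adjusted p = 0.832), and TP53INP1 did not pass (adjusted p = 0.094; 0.037 without day 3 replicate 3). The p53 median was -0.04 while its mean was 0.03 and camera's direction was up, and the median was 0.02 with library totals alone. Adjusted over the list alone, 1 gene each of the coagulation, heat shock and p53 lists passed. Plasma protein genes that rose numbered 2 without day 3 replicate 1. Plasma protein genes that fell numbered 4 without day 3 replicate 1 and 1 without day 3 replicate 2. The coagulation count was 4 without day 3 replicate 2 and 0 without day 3 replicates 3 or 4 or day 5 replicates 1, 3 or 4. Coagulation genes that rose numbered 2 without day 3 replicate 1. The glucocorticoid count was 5 without day 3 replicate 1 and 0 without day 3 replicate 4 or day 5 replicates 1 or 4. Glucocorticoid genes that rose numbered 1 without day 3 replicate 1. The glycolysis count was 5 without day 3 replicate 1, 1 without day 3 replicate 4 or day 5 replicates 1 or 2 and 0 without day 5 replicate 4. Glycolysis genes that fell numbered 1 without day 3 replicates 1 or 2. The heat shock count was 2 without day 3 replicate 1 and 0 without day 3 replicate 4 or day 5 replicates 1, 2, 3 or 4. The p53 count was 2 without day 3 replicate 1 and 0 without day 5 replicate 4. P53 genes that fell numbered 1 without day 3 replicate 3.

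Several lists with no call differed more between day 3 libraries than between days. Acute phase proteins, which the liver secretes in inflammation, had none of 14 genes past the test in edgeR (0 at an unadjusted p under 0.05, 0 in DESeq2 and 0 in limma-voom). Their median was -0.21 although camera's direction was up (adjusted p = 0.589; 8.0e-04 without day 3 replicate 1). Their score was 1.27 in day 3 replicate 1, between -0.998 and -0.19 in the other day 3 libraries and between -0.11 and 0.24 on day 5. The unfolded protein response list, with none of 26 past the test in edgeR (2 at an unadjusted p under 0.05, 0 in DESeq2 and 0 in limma-voom; adjusted p = 0.433), had a median of 0.05, a mean of -0.09 and camera's direction up. Its score was 0.76 in day 3 replicate 1 and -0.42 to -0.07 in the other day 3 libraries, and the list passed without that library (adjusted p = 6.7e-06). Metallothioneins had none of 8 past the test in edgeR (1 at an unadjusted p under 0.05, 1 in DESeq2 and 0 in limma-voom; list adjusted p = 0.163; 0.021 without day 3 replicate 1, 0.0301 without day 3 replicate 2). Their scores were 0.64 and 0.43 in day 3 replicates 1 and 2 and -0.83 and -0.75 in day 3 replicates 3 and 4. Without day 3 replicates 1 and 2, 9 acute phase, 16 unfolded protein response and 8 metallothionein genes rose, and 1 unfolded protein response gene fell. These libraries had the highest day 3 scores for each of these lists. Leaving them out, which was chosen after seeing the data, therefore favours a rise. Acute phase genes that rose numbered 4 without day 3 replicate 1. Unfolded protein response genes that rose numbered 10 without day 3 replicate 1. Metallothionein genes that rose numbered 1 without day 3 replicate 2.

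No gene of the remaining lists passed in edgeR. These were 26 interferon-stimulated genes (1 at an unadjusted p under 0.05, 1 in DESeq2 and 0 in limma-voom; list adjusted p = 0.944) and 30 genes of nuclear oxidative phosphorylation (2 at an unadjusted p under 0.05, 1 in DESeq2 and 0 in limma-voom; list adjusted p = 0.589), whose medians were -0.06 and -0.02. Of 13 mitochondrially encoded genes none passed (1 at an unadjusted p under 0.05, 0 in DESeq2 and 0 in limma-voom; median 0.14, list adjusted p = 0.216; 0.029 without day 3 replicate 4). Of 15 genes of iron handling none passed (4 at an unadjusted p under 0.05, 1 in DESeq2 and 0 in limma-voom; list adjusted p = 0.973), with a median of -0.04 and camera's direction up. Of 7 histone and small nuclear RNA genes none passed (2 at an unadjusted p under 0.05, 0 in DESeq2 and 0 in limma-voom; median -1.04, list adjusted p = 0.119; 0.028 without day 3 replicate 3). With library totals alone the medians of oxidative phosphorylation and iron handling were above 0 (0.04 and 0.01). Interferon genes that rose numbered 2 without day 3 replicate 1. Interferon genes that fell numbered 2 without day 3 replicate 1. Mitochondrial genes that fell numbered 2 without day 3 replicate 1. Iron genes that rose numbered 2 without day 3 replicate 1. Iron genes that fell numbered 1 without day 3 replicates 1 or 2.

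**Figure D3:**
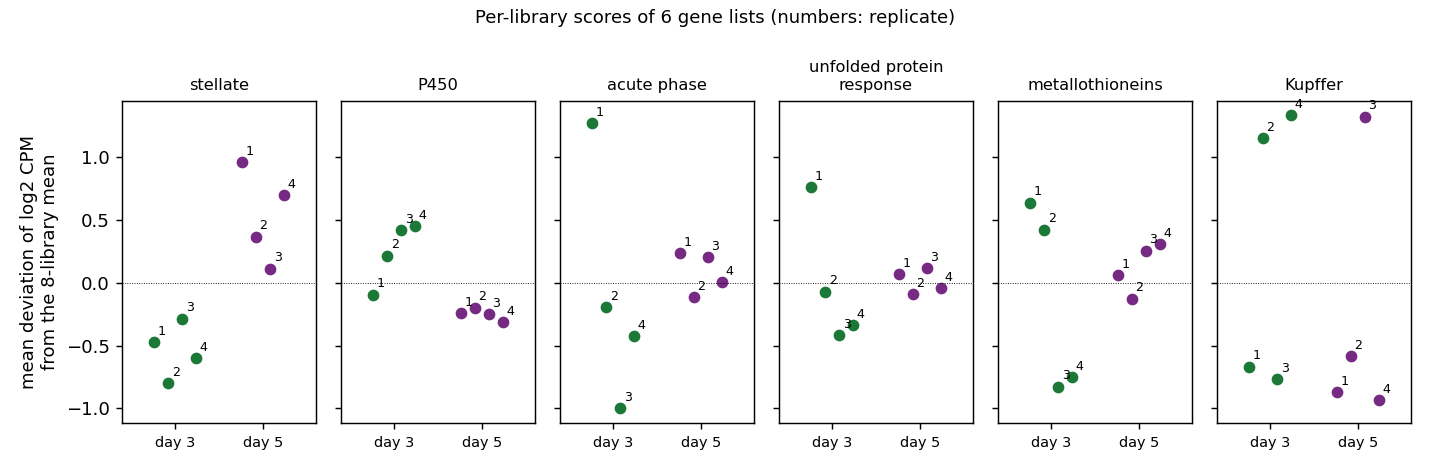
Each panel shows 1 list and each point 1 library, with day on the x axis, the mean deviation of log2 CPM from the 8-library mean on the y axis and the replicate number beside the point. The stellate scores of the 4 day 5 libraries (0.11 to 0.96) lie above all day 3 libraries, day 3 replicate 1 is highest for acute phase (1.27) and unfolded protein response (0.76), and 3 libraries of both days have high Kupffer scores (1.15 to 1.34).

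Of the genes named for the size of their change, CHI3L1, a secreted chitinase-like glycoprotein, gave 7.71 ± 4.92 and 28.6 ± 7.03 CPM (log2 1.91, adjusted p = 0.027; 0.056 to 0.092 without day 3 replicates 2 and 4 and day 5 replicates 1, 2, 3 and 4 in turn). SVEP1, an extracellular matrix protein, rose by log2 1.88 (adjusted p = 0.018; 0.065 to 0.068 without day 5 replicates 1 and 4 in turn), GREM1, a secreted BMP antagonist, by 1.78 (adjusted p = 0.015; 0.055 to 0.066 without day 5 replicates 1 and 4 in turn), and ADAMTS2, a procollagen-processing protease, by 1.76 (adjusted p = 0.011; 0.052 without day 5 replicate 4). SLC6A12, a betaine transporter, fell 2.84-fold and was called in all 8 fits that left out 1 library (12.7 ± 3.57 and 4.48 ± 0.557 CPM, log2 -1.51, adjusted p = 0.0086). AQP7, a glycerol channel, fell by 1.298 on the log2 scale (adjusted p = 0.027; 0.069 to 0.104 without day 5 replicates 1, 2, 3 and 4 in turn). HSD17B14, a steroid dehydrogenase, fell by 1.27 (adjusted p = 0.038; 0.0604 to 0.129 without day 3 replicates 3 and 4 and day 5 replicates 1, 2, 3 and 4 in turn), and USP2, a deubiquitinase, fell by 1.23 (adjusted p = 0.024; 0.057 to 0.093 without day 3 replicate 4 and day 5 replicates 1, 2, 3 and 4 in turn).

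**Figure D4:**
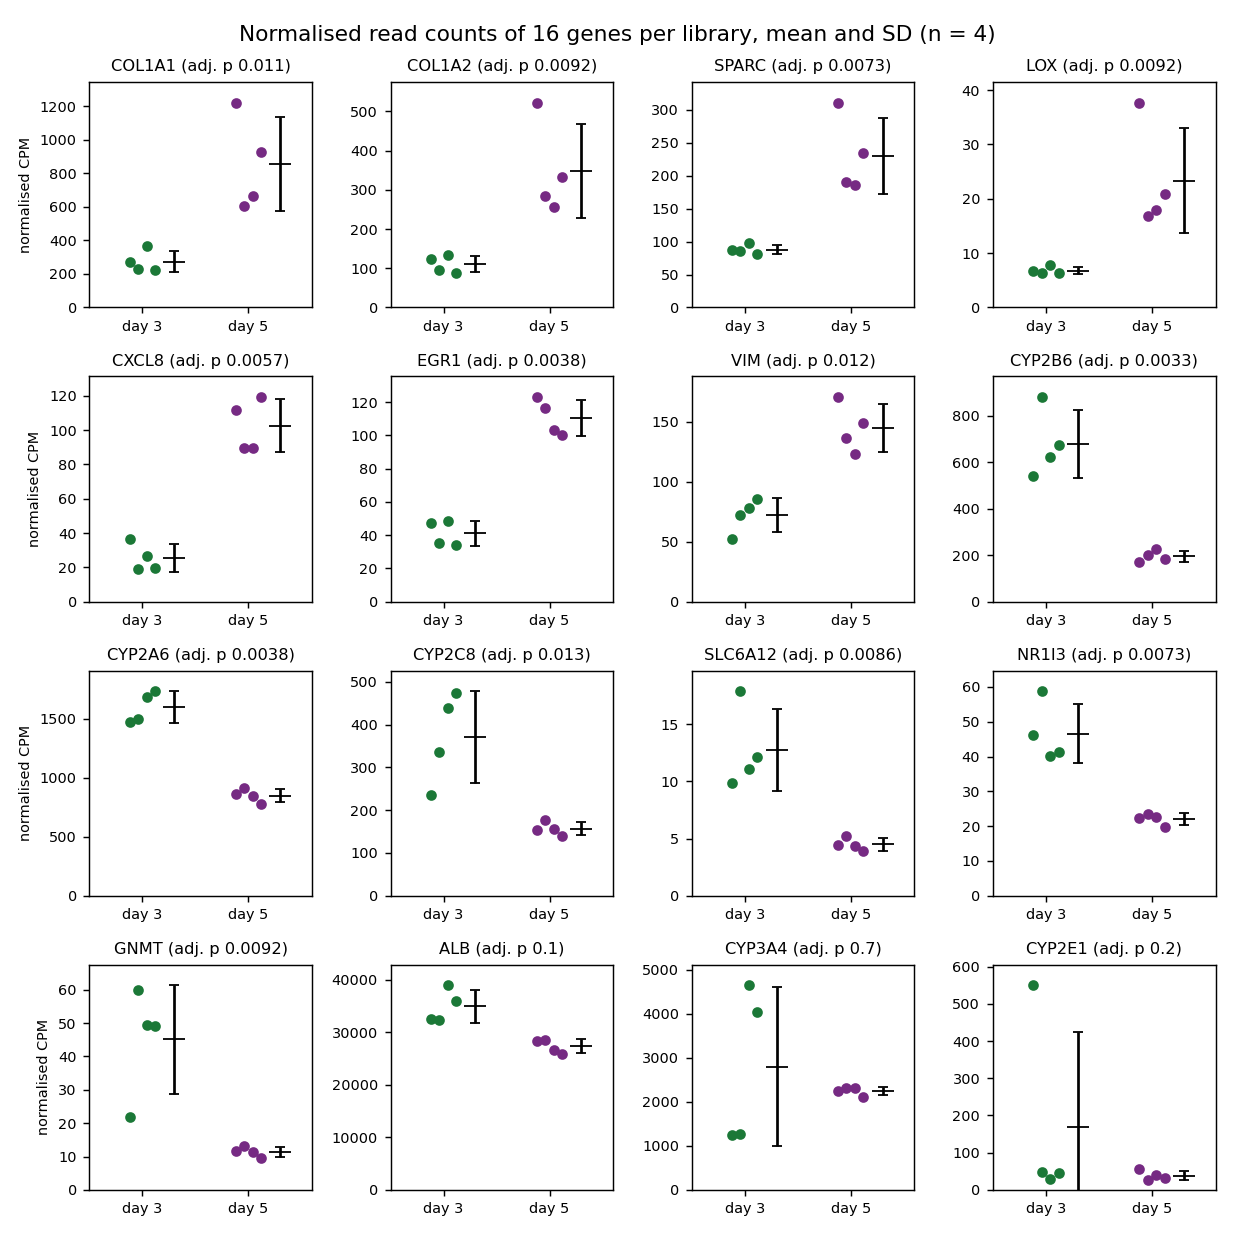
Normalised CPM (y axis, from 0) of 16 named genes in the 4 libraries of each day (points), with the mean and SD as a black bar beside them (not drawn below 0, as for CYP2E1 on day 3) and the edgeR adjusted p in each title. Points of both days do not overlap for the 14 genes from COL1A1 to ALB, although ALB did not pass (adjusted p = 0.103), and the day 3 libraries are split for CYP3A4 (1254 and 1263 against 4648 and 4033).

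The list test assumed a correlation of 0.01 between genes. With it 24 of 39 lists passed, 10 higher and 14 lower. With the correlation estimated from the data 0 passed camera (11 of the 24 at an unadjusted p under 0.05), and the rotation test fry, which does not compare a list with other genes, called 20. Fry left out the inflammatory (adjusted p = 0.2025), phase II (0.1006), endothelial (0.3262) and plasma protein (0.1468) lists. Exact permutation tests of the list scores between days, which were not fixed beforehand, passed for no list (adjusted p of 0.0696 or more). The stellate, matrix, P450, cholesterol and ribosomal lists were among those at the smallest p this test allows, 0.0286 (adjusted 0.0696). Adjusted over 39 lists, a pass needed most lists to reach that value. The permutation tests therefore do not show that no list differed. Of the 35 ways to split these libraries 4 against 4, 3 gave 24 lists or more, the real split included, and the highest other split gave 30.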

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

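The tests of acute phase scores against P450, Kupffer and unfolded protein response scores, the fits without day 3 replicates 1 and 2, and the comparison of histone scores were chosen only after the result was seen. The rules for reading the P450 and Kupffer tests were also changed once their values were known. Under the rule first written, an adjusted p of 0.05 or more counted against an explanation, and the P450 relation would have been argued against; it is left open here because missing the threshold with 8 libraries does not show that there is no relation. Both rules count against the Kupffer explanation, and the same limit of 8 libraries holds for it. Values of single libraries were compared with the other 3 libraries of their day by Dixon's test, over 162 groups of 4 values. Chance flags about 1 in 20 groups, or 8.1 of these, and 13 stood apart.

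Of these, 5 concerned day 3 replicate 1. CYP2E1 stood at 550.4 CPM there against 29.3 to 47.7 in the other day 3 libraries. CYP1A2 stood at 115 CPM against 759 to 887, and GLS2 at 4.33 CPM against 8.99 to 9.83. TUBB6 stood at 24.75 CPM against 24.35 to 24.41, a gap that is small beside its level. The 10 most abundant genes of this library took 14.8% of its counts against 11.3 to 11.9%. In day 3 replicate 2, ABCC2 stood at 885 CPM against 736 to 759, and AQP7 at 19.02 against 8.402 to 9.79. KRT19, a biliary keratin, was low in day 3 replicate 3 (15.8 CPM against 33.3 to 36.8) and high in day 5 replicate 4 (47.98 CPM against 25.01 to 27.99). In day 5 replicate 1, SVEP1 stood at 22.5 CPM against 13.8 to 14.6 and CHI3L1 at 39.1 against 23.8 to 25.9. CD163 stood at 31.9 CPM in day 5 replicate 3 against 10.3 to 11.7. The protein-coding share of day 5 replicate 2 was 98.63% against 98.71 to 98.72% in the other day 5 libraries.

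The day 3 libraries lay farther from each other than the day 5 libraries, by a ratio of within-day distances of 1.485. The share of assignments of libraries to days with a ratio as large was 0.0143. This share counts large ratios only and is the smallest that such a count can give, so it is no strong support. Fewer counts in some libraries and a trend with GC content are argued against as whole causes, since the ratio was 1.495 with all libraries thinned to the smallest total and 1.488 after the GC correction. Without day 3 replicate 1 the ratio was 1.24, between the bounds set beforehand (below 1.1 if this library were the cause, at least 1.3 if not), so that the part this 1 library plays stays open. Without day 3 replicates 1 and 2 the ratio was 0.977, and these libraries also had the highest scores for histone and small nuclear RNA genes without poly(A) tails (0.64 and 0.93, against -0.42 and -0.08 in day 3 replicates 3 and 4). A difference between libraries in RNA quality or selection, or between chips in culture, handling or state may therefore remain, untested here, and the labels give no batch.

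Acute phase genes varied between libraries of 1 day, most of all in day 3 replicate 1. The rule counted against a difference between chips in Kupffer cell content. The day-centred acute phase and Kupffer scores correlated at r = -0.122 over 8 libraries (exact permutation p = 0.92, adjusted 0.92, with rho = -0.024, exact p = 0.981, and r = -0.108 without day 3 replicates 1 and 3). The library with the highest acute phase score had a Kupffer score below its day's mean. With 8 libraries this does not exclude a weaker relation. An acute phase state with low P450 genes may be a candidate explanation that stays open, at r = -0.919 (exact p = 0.0538, adjusted 0.0807; rho = -0.762, exact p = 0.0521, adjusted 0.0781), since neither passed and r was -0.64 without those libraries. Acute phase and unfolded protein response scores correlated at r = 0.982 (exact p = 0.00347, adjusted 0.0104; rho = 0.952, exact p = 0.00521, adjusted 0.0156), and at 0.951 without those libraries. These 3 correlations were tested by 576 permutations within days, whose smallest p is 0.00174, and a difference in state between chips stays open as untested.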

How the results depend on the processing

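The fit without day 3 replicates 1 and 2 was chosen only after the result was seen; the other alternatives were fixed beforehand. The count of 938 genes stayed within 1.5 times under RLE, upper quartile and library-total scaling, both other filters, limma-voom, the GC correction and removal of mitochondrially encoded genes (788 to 951). Under the 3 other scalings the median of the shifts of single genes was at most 0.0556 on the log2 scale. Library totals alone called 227 genes lower. DESeq2 called 1987 (1056 higher and 931 lower). In the simulated data, drawn with edgeR's dispersion estimates, DESeq2 made 51 false calls among 255 against 8 among 180 for edgeR. The threshold of 0.01 left 96 (49 and 47) and the test against a fold of 1.5 left 2 (1 and 1), both stricter by construction. Without day 3 replicates 1 and 2 there were 5019 (2589 and 2430). The count with estimated correlation in camera was 0 lists. The cause was not tested for the shifts under DESeq2, library totals, the left-out libraries and the estimated correlation.

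With the replicate number as a block, 54 genes were called (30 higher and 24 lower), and with the GC correction added 50 (30 and 20). The numbers did not pair the samples: deviations from the day means of same-numbered libraries correlated between -0.269 and 0.021, and 0 of 8 libraries correlated best with its own number. The block takes up degrees of freedom; the cause of the lost calls was not tested further. Of 75 genes chosen by rule, 33 kept their side of the threshold under the block and 42 did not.

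Leaving out 1 library at a time gave 106 to 2041 genes (57 to 999 higher, 49 to 1042 lower) and 22 to 28 lists. The log2 fold change of CYP3A4 ran from -0.566 to 0.0475 and that of KRT19 from -0.212 to 0.158, crossing 0. Lists whose direction turned in some of these fits had these ranges of adjusted p: 8.00e-04 to 0.933 for acute phase, 6.11e-04 to 0.996 for complement and coagulation, 0.655 to 0.993 for glucocorticoid-responsive genes, 0.597 to 0.9698 for interferon-stimulated genes, 0.468 to 1 for iron handling, 0.0294 to 0.911 for mitochondrially encoded genes, 0.416 to 0.933 for p53 targets, 0.297 to 0.738 for sinusoidal markers and 6.70e-06 to 0.933 for the unfolded protein response. The day difference in total count ran from -1137170 to 4941180 and that in genes at 1 CPM from -50.6 to 110.4. Other reversals were CYP1A2 (log2 0.0885 with limma-voom and 0.0203 with the block and GC correction), iron handling (adjusted p = 0.964 with fry and 0.8399 with the 1 CPM filter) and interferon-stimulated genes (0.984 with the block). Without day 3 replicates 1 and 2, CYP2E1 turned to log2 0.0355, and iron handling (adjusted p = 0.775), interferon-stimulated (adjusted p = 0.555), glucocorticoid-responsive (adjusted p = 0.676), mitochondrially encoded (adjusted p = 0.134) and histone genes (adjusted p = 0.836) turned as lists, none past the threshold in either direction. The adjusted p of 1 such gene was missing in DESeq2, and 2 fits of such genes could not be tested. At these depths a count of 3 equals 0.0534 to 0.0791 CPM, and depth limits genes near this floor.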

Other observations

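The test of a lower hepatocyte share and the score differences were chosen only after the result was seen, and the genes of the next sentences were chosen after their values were seen from calls made in all 8 fits that left out 1 library. CCND2, which encodes cyclin D2 of the G1 phase, rose from 0.352 ± 0.116 to 2.27 ± 0.264 CPM (log2 2.65, SE 0.24, adjusted p = 0.0034), and PLAT, which encodes tissue plasminogen activator, from 3.87 ± 0.212 to 8.96 ± 1.64 CPM (log2 1.21, adjusted p = 0.0073). FAP, the fibroblast activation protein, rose by log2 2.06 (adjusted p = 0.0092), and CCDC80, a matrix-associated secreted protein, by 1.55 (adjusted p = 0.0086). BICC1, an RNA-binding protein, rose by 1.48 (adjusted p = 0.0092) and CDK5RAP2, a centrosomal protein, by 0.90 (adjusted p = 0.0033).

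Among genes outside the lists that fell, AGXT, the peroxisomal aminotransferase that detoxifies glyoxylate, went from 882 ± 49.6 to 464 ± 36.96 CPM (log2 -0.93, SE 0.08, adjusted p = 0.0033). ALDH6A1, of valine catabolism, fell by 0.79 on the log2 scale (adjusted p = 0.0086), SELENBP1, a selenium-binding protein, by 0.92 (adjusted p = 0.0086) and HGFAC, the activator of hepatocyte growth factor, by 0.63 (adjusted p = 0.0054). MIR122HG, the host transcript of the hepatocyte microRNA miR-122, fell from 26.3 ± 5.95 to 10.3 ± 1.897 CPM (log2 -1.36, adjusted p = 0.0092).

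On day 5, 16 of 30 matrix genes and 11 of 22 stellate markers were higher and 9 of 20 P450 genes lower. These lists passed with the preset but not with the estimated correlation, and 2 explanations were weighed. The labels give no batch, so a batch in handling or sequencing that went with day could not be told apart from day. A lower share of hepatocyte RNA as the whole cause would raise markers of every other cell type alike. The stellate minus endothelial score was 0.906 higher on day 5 (SDs 0.269 and 0.463, n = 4 each, exact permutation p = 0.0286, the smallest this test allows). This p was not adjusted over the score differences. Stellate minus Kupffer, at 1.603, did not pass (exact permutation p = 0.171). The stellate and endothelial lists thus changed unlike each other, which this cause alone would not give. The contrast was picked after their medians were seen, so that its p-value is no separate support. A trend with GC content is argued against, since 32 of 32 calls of these lists were also made after the GC correction (811 of 938 over all genes). P450 minus plasma protein scores differed by -0.397 (exact p = 0.143), which did not pass, so that a change in hepatocyte share together with a change within cells may remain. A rise in stellate cells or their matrix programme with days in culture stays open as untested.

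Of the 35 splits of the 8 libraries into 4 against 4, only the real 1 gave 938 genes, and every other split gave 0. Every other split sets libraries of both days on 1 side, so that a difference between days adds to its spread and lowers its count. A share of 1 in 35 is the smallest this test can give. It argues against an arbitrary division as the source of the gene count but does not exclude it. For the lists, 3 of 35 splits gave 24 or more, the highest other 30, which set day 3 replicate 1 with day 5 replicates 1, 3 and 4 against the other 4 libraries. Another split, with 27 lists, set day 3 replicate 1 with day 5 replicates 1, 2 and 4. Both of these keep most of the division by day, so they are poor examples of an arbitrary division. Splits with 2 libraries of each day on a side gave 3 to 16 lists. This test can therefore not decide how many lists chance gives, and chance is not excluded for their number.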
